A study of Mus musculus with 24 samples.

How the data were processed

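Tibialis anterior muscle of mice aged 6 months was profiled on arrays. Per the labels' protocols, the muscles were dissected, frozen and extracted with Trizol, and labelled total RNA was hybridised. The label field names Cy3 while the labelling protocol names Cy5, so the dye is not settled. The genotypes were Myf6 cre/+; Hira flox/+ for the 4 control animals and Myf6 cre/+; Hira flox/- for the 4 knockout animals, on a mixed background of C57BL6/J and 129S1/SvImJ. The RNA of each animal was hybridised 3 times, which gave 24 arrays. Animals were numbered 1 to 4 within a group in the order of the deposit, and these numbers pair nothing across groups.

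The deposited table held 1 linear probe intensity per array for 26423 rows. The scanner, the background correction and the scaling are not given in the sources used here. All 24 columns of deposited intensities had the same median of 626.429, so the authors' values had been scaled to a common median, and between 0% and 5.37% of the values of an array lay at or below 0, as after a subtraction of background. The 5th percentile of an array ranged from -2.35 to 125, so the low end of the scale differed between arrays. The number of arrays and animals, and not a counting depth, limits the precision of these values.

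Values below the 5th percentile of all deposited values, 38.8, were set to that floor, which was chosen after the unit was known and before any test, and log2 was taken. The 3 hybridisations of an animal were averaged, so the animal was the replicate. The probe annotation, which is old, gave 1 symbol for 20377 rows, several for 0 and none for 6046. Symbols were brought up to date through a RefSeq gene table of assembly GRCm38.p6, in which 18213 rows matched a current symbol and 2126 the synonym of 1 gene. The other 38 rows with a symbol matched neither and kept their annotated name. The row with the highest mean over all arrays stood for a gene with more than 1 row, which left 17742 genes. No build is named for the array, so no coordinates are given, and the gene table served only for names, gene type and gene order.

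The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the 8 animal means), and p-values were adjusted with the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Folds are 2 to the power of the difference of log2 means. A gene whose level in a group was no higher than 125, the highest 5th percentile of any array, was treated as dim there, and its fold is given as a lower bound against that level. Of 43 gene lists fixed before the data were examined, the 41 with at least 5 measured members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The genes named in the text are Hira, the 12 rises and 12 falls of largest size among genes that passed the test with no overlap between groups, and up to 4 members of each list by smallest p (2 where none passed), all by a rule set before the data were examined; predicted genes were counted but not named among the largest changes. Other genes are said to be chosen after their values were seen.

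The alternatives were quantile normalization, median centring, cyclic loess, a filter on dim rows, the mean over the rows of a gene, every row as a feature, all arrays with the animal as a random block with and without the hybridisation number as a block, the median of hybridisations, an intensity trend with robust variances, array weights, the series of animal numbers as a block and each series alone, leaving out each animal or hybridisation number, ordinary t statistics, a fold filter, an added constant in place of the floor, and other set tests. A higher floor and the removal of the 2 arrays of highest background were added after seeing the data. On simulated data for 17742 genes, with 4 animals against 4 and the spread of the real genes, 50 genes were changed at each size. The fit recovered 22% of those changed by 0.5 on the log2 scale, 68% at 1, 98% at 2 and 100% at 4, with 4 false calls among 148. These changes were placed in brighter genes only, with independent noise for each gene and a smaller share of changed genes than in the data. The rates thus do not describe dim or correlated genes.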

Results

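HIRA is a chaperone that places the histone variant H3.3 in chromatin outside DNA replication. The series asked how its loss in myofibres, through a Cre recombinase expressed from the Myf6 locus, changes the transcripts of the mouse tibialis anterior at 6 months of age. Control animals carried 1 floxed and 1 intact copy of Hira, and knockout animals 1 floxed and 1 null copy. Both groups carried the Cre, so by genotype control fibres kept 1 intact copy. The null copy of the knockout lay in all its cells, not in fibres alone. There were 4 animals per group and 3 hybridisations per animal. Pairs of arrays of the same animal correlated at 0.985 to 0.995 over genes, pairs from different animals of a group at 0.976 to 0.993, and pairs from different groups at 0.968 to 0.987. The median SD of a gene was 0.178 (log2) between hybridisations of an animal and 0.204 between animal means of a group. The second value still holds spread between hybridisations, and with that removed it was 0.149. In 65.5% of genes the variance between hybridisations was above that between animals. The first principal component of the animal means held 40.9% of the variance, and all 4 control animals lay below 0 on it and all 4 knockout animals above 0.

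The difference at the Hira probe did not pass the test. Its mean log2 intensity was 8.97 ± 0.11 (SD, n = 4 animals) in control and 8.82 ± 0.35 in knockout muscle, a difference of -0.15 (95% interval -0.51 to 0.22; limma, adjusted p = 0.623). An exact two-sided permutation test gave p = 0.457, where the smallest p possible is 0.0286. Knockout animal 2 (9.31) lay above every control animal (8.85 to 9.11), and the other knockout animals lay below every control animal. The difference was -0.31 without knockout animal 2 (limma, adjusted p = 0.171) and -0.047 without knockout animal 3 (adjusted p = 0.912). The place of this probe relative to the deleted part of the gene is not given in the sources used here, so the value does not check the genotypes. Whole muscle also holds cells other than fibres, and by genotype these carried a null copy of Hira in the knockout alone.

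Knockout muscle held far more of the imprinted non-coding RNA H19 and of the phosphatase inhibitor-like gene Ppp1r14bl than control muscle, and several times less of the transcription factor Tbx1 and the inositol phosphatase Inpp5j. H19 rose 21.9-fold, from an intensity of 16892 to 370180 (log2 fold change 4.45 ± 0.16, SE; adjusted p = 2.2e-07, limma). The upper level lay near the array maxima of 437047 to 761817, where the response of the array is not known to be linear. Ppp1r14bl rose 23.6-fold (4.56 ± 0.30; adjusted p = 2.0e-05), although a second row for it gave 2.55 on the log2 scale. Tbx1 fell 4.64-fold (log2 fold change -2.21 ± 0.15; adjusted p = 2.0e-05), and a second row for it gave -2.16. Inpp5j fell 5.27-fold (-2.40 ± 0.22; adjusted p = 0.00010). In each of these 4 genes all 4 knockout animals lay on one side of all 4 control animals.

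In total 1647 of 17742 genes, or 9.28%, changed at an adjusted p under 0.05, 759 higher and 888 lower in knockout muscle, and 4264 had an unadjusted p under 0.05. The balance of directions turned under cyclic loess (1318 higher and 1136 lower), without control animal 1 (578 and 484), knockout animal 3 (527 and 418), knockout animal 4 (629 and 587) or hybridisation 2 (598 and 505), and in each series of animal numbers alone (51 and 11; 311 and 197). Changes of 2-fold or more were more often rises (225) than falls (86). The groups did not overlap in 3096 genes, 17.5% of those tested, where chance gives 2.86%. Under the naming rule, which leaves out predicted genes, the next largest rises were those of Aldh1a7, an aldehyde dehydrogenase (14.3-fold), and Tecta (10.3-fold). They were followed by the small GTPase Rab15 (9.0-fold), the photoreceptor membrane protein Rom1 (7.86-fold), Ppfia3 (at least 5.30-fold) and Tlcd2 (6.78-fold). Ostn, which encodes the muscle-secreted peptide musclin (5.76-fold), Pifo (5.50-fold), Rasl10b (at least 4.17-fold) and the carbonic anhydrase Car1 (5.35-fold) came next. The other rows of Car1 gave 0.17 and -0.31 on the log2 scale. Arrdc2 fell 5.62-fold, a size that rests largely on control animals 2 and 3 (14.43 and 14.18 on the log2 scale). Control animals 1 and 4 lay at 11.85 and 12.10, and the highest knockout animal at 11.35. Misp3 fell 4.17-fold, Zbtb11os1 3.97-fold and Raver2 3.81-fold. Tmem132b fell 3.41-fold (log2 fold change -1.77, with -0.41 and -0.33 in its other rows). Pck1, an enzyme of glyceroneogenesis and gluconeogenesis, fell 3.34-fold, and Phkg1, the catalytic subunit of muscle phosphorylase kinase, 3.18-fold. Flrt1 fell 3.10-fold (-1.63, with -1.19 in its other row), Ccdc69 2.83-fold and Tmem74b at least 1.41-fold. The count of changed genes was 1062 without control animal 1 and 945 without knockout animal 3, and within the 2 series of animal numbers it was 62 and 508, with 2 animals per group in each.

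**Figure D1:**
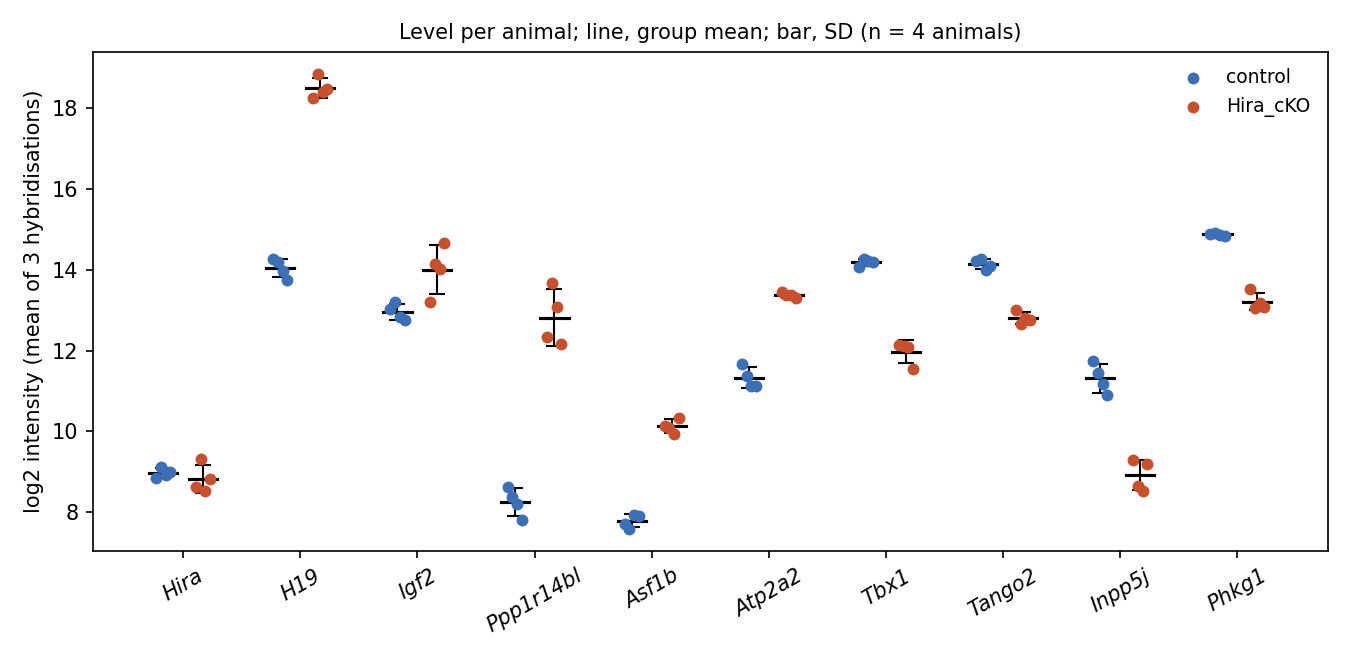
Log2 intensity of 10 genes (y axis) in each of the 8 animals, with control in blue and Hira knockout in orange; each point is the mean of 3 hybridisations, horizontal lines are group means and bars are SDs over 4 animals. Hira overlaps between groups (8.97 against 8.82), H19 rises from 16892 to 370180 in intensity, and Tbx1, Tango2, Inpp5j and Phkg1 lie lower in every knockout animal.

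Some slow-fibre calcium-handling and contractile genes rose. Of 13 measured slow-twitch fibre genes, 5 rose and 1 fell (the same counts adjusted over the list alone), with a median log2 fold change of 0.19. Atp2a2, the slow-type sarcoplasmic calcium pump, rose 4.13-fold, although its other rows gave -0.44 and 1.80. Casq2 rose 2.37-fold, Sln, a regulator of that pump, 2.35-fold and Tnni1, slow troponin I, 2.01-fold. Pln, another regulator of the pump, fell 1.56-fold. The list passed camera (adjusted p = 0.00975), with adjusted p = 0.515 with an estimated correlation. Its median was 0.31 under quantile normalization and 0.32 under cyclic loess, and the call was lost without control animal 4 (median 0.054; adjusted p = 0.0856) and in series A of the animal numbers alone (-0.020; 0.292). Of 9 fast-twitch genes 0 rose and 0 fell, over all genes and adjusted over the list alone; Pvalb stood at -0.35 ± 0.19 (log2, SE) and Casq1 at -0.21 ± 0.13. The fast-twitch genes had levels between 181960 and 412300, near the array maxima of 437047 to 761817, and the difference between the slow and fast lists was not tested. Among 26 calcium handling genes 3 rose and 1 fell, with the same counts adjusted over the list alone. Among 25 sarcomere genes Lmod3 rose 1.42-fold and Ankrd23 fell 1.62-fold.

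Genes of the neuromuscular junction and of denervated muscle also rose in part. Of 22 measured, 6 rose and 1 fell (7 and 3 adjusted over the list alone), with a median log2 fold change of 0.10. Lrp4, the agrin receptor of the postsynaptic membrane, rose 2.27-fold, acetylcholinesterase Ache 2.01-fold and the acetylcholine receptor subunit Chrna1 1.56-fold. The fetal receptor subunit Chrng fell 1.59-fold. The list passed camera (adjusted p = 0.0155; adjusted p = 0.515 with an estimated correlation) and lost its call under quantile normalization (median 0.12; adjusted p = 0.0973), cyclic loess (0.13; 0.0687) and without knockout animal 4 (0.087; 0.0803). In series A alone the median turned to -0.0097 (adjusted p = 0.599).

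Of 11 embryonic and regenerating fibre genes, H19 and Igf2 rose and Chrng fell (4 rose and 2 fell adjusted over the list alone). Igf2, a growth factor gene that neighbours H19, rose 2.08-fold (log2 fold change 1.06 ± 0.26; adjusted p = 0.026), a call that was lost without any 1 of 5 animals. Of 17 imprinted genes, 2 rose (H19 and Igf2) and 2 fell, Impact by 1.32-fold and Dlk1 by at least 1.31-fold, although another row of Dlk1 gave 0.23 (log2); adjusted over the list alone, 2 rose and 3 fell. Neither list passed camera. H19 ranked between 10 and 36 by intensity on the knockout arrays and between 1296 and 1776 on the control arrays.

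Among 13 genes of the HIRA complex and other H3.3 chaperones, Asf1b, a histone chaperone that hands H3 and H4 to assembly factors, rose 5.07-fold (log2 fold change 2.34 ± 0.13; adjusted p = 7.0e-06) and Chaf1a, the large subunit of the replication-coupled assembly factor, fell 1.38-fold; adjusted over the list alone, 1 rose and 3 fell. Of 6 measured genes of the list fixed as H3.3 and other replication-independent histones, H2ax fell 1.72-fold and H2aw 1.42-fold. The log2 fold change of H2aw was -0.51, with -0.23 in its other row. Whether each listed histone gene, H2aw and H2ax among them, is made outside replication was not checked. Some genes beside Hira on chromosome 16 were lower. Of 21 measured neighbours, from 24 fixed, 3 fell and 0 rose, with the same counts adjusted over the list alone: Tbx1, Tango2 (2.53-fold) and Arvcf (1.86-fold). The list passed camera (adjusted p = 0.0474; adjusted p = 0.515 with an estimated correlation), and the call was lost under quantile normalization (median -0.12 against -0.15; adjusted p = 0.0973) and cyclic loess (-0.099; 0.0714).

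**Figure D2:**
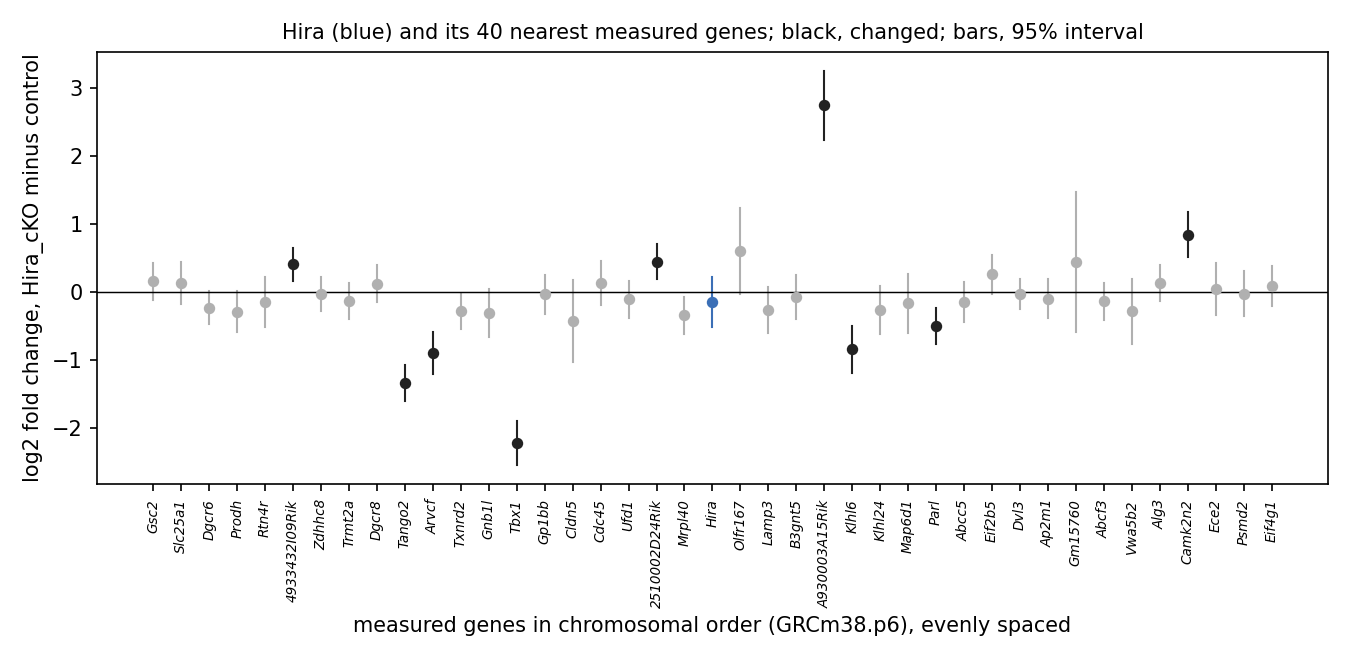
Log2 fold change, knockout minus control (y axis), of Hira (blue) and of the 20 measured genes on each side in the gene order of assembly GRCm38.p6 (x axis, evenly spaced); bars are 95% intervals and black marks genes that changed. Of the 40 genes around Hira 9 changed, and Tbx1 lies lowest at -2.21.

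Some genes of fuel metabolism fell. Of 27 fatty acid oxidation genes 9 fell and 0 rose (12 fell adjusted over the list alone), with a median log2 fold change of -0.31, among them the carnitine transporter Slc22a5 (2.04-fold), Eci1 (1.81-fold), the dehydrogenase Acadl (1.77-fold) and Etfa (1.60-fold). This list passed camera with an adjusted p of 0.000574 (adjusted p = 0.515 with an estimated correlation) and also passed fry (adjusted p = 0.0166). Of 24 glycolysis and glycogen genes 3 fell and 0 rose (7 fell adjusted over the list alone), namely Phkg1, Ppp1r1a (3.19-fold) and Pfkfb3 (1.53-fold), with adjusted p = 0.00326 and adjusted p = 0.515 with an estimated correlation. Of 39 oxidative phosphorylation genes 6 fell and 0 rose (9 fell and 1 rose adjusted over the list alone), led by the complex I subunits Ndufs3 (1.65-fold) and Ndufa4 (1.54-fold). That list had an adjusted p of 0.00492, with adjusted p = 0.825 with an estimated correlation, and was lost under quantile normalization (median -0.11 against -0.22; adjusted p = 0.0687) and cyclic loess (-0.10; 0.0518). Of 23 citric acid cycle genes 3 fell and 2 rose, with Idh3g down 1.62-fold and Mdh1 up 1.70-fold (5 fell and 2 rose adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0878). Sirt3, a mitochondrial deacetylase, fell 1.69-fold and the myokine gene Il15 1.86-fold. Of 22 ribosomal protein genes 5 rose and 0 fell (6 rose adjusted over the list alone), with Rpl5 up 1.81-fold and Rplp0 up 1.51-fold. Their list passed camera at adjusted p = 0.00158 (adjusted p = 0.515 with an estimated correlation), and fry gave adjusted p = 0.0706.

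**Figure D3:**
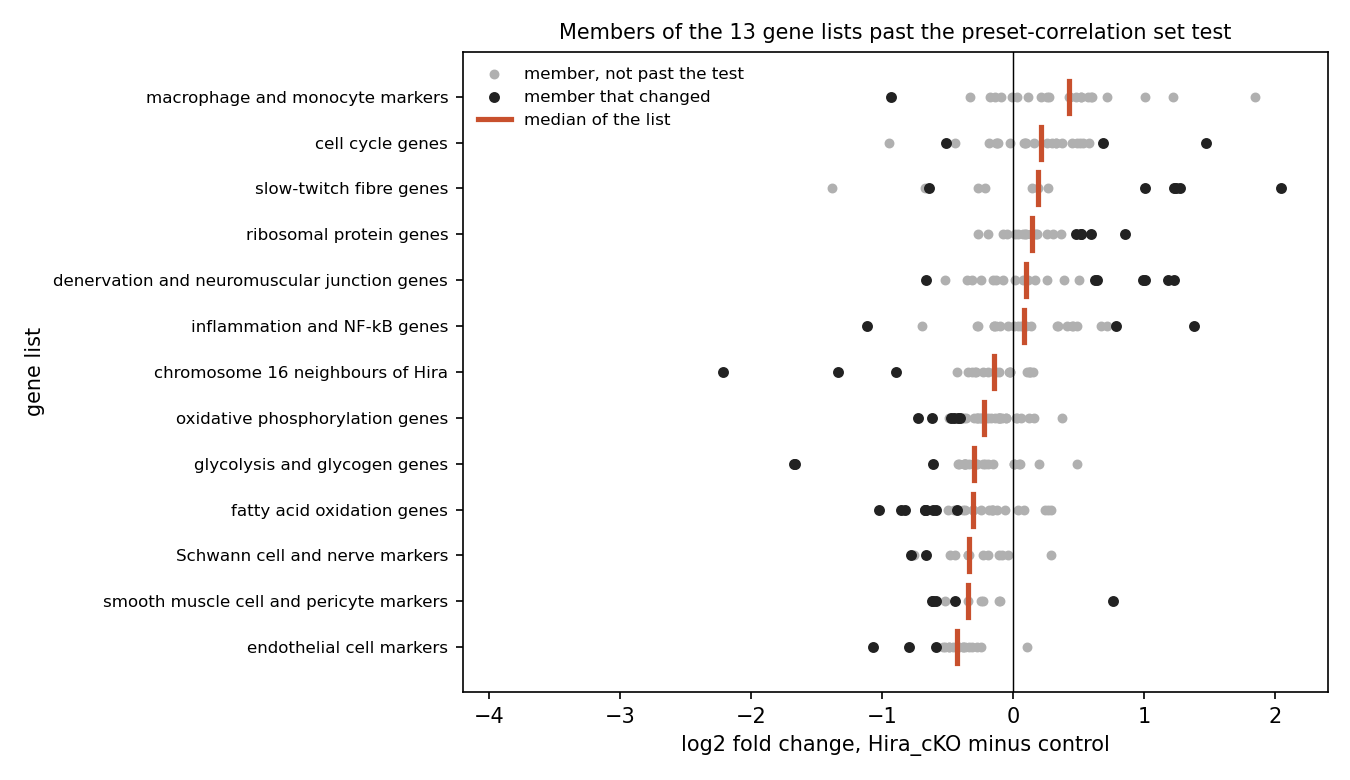
Log2 fold change, knockout minus control (x axis), of each measured member of the 13 gene lists past the preset-correlation test (y axis); black points changed, grey points did not pass, and the orange bar is the median of the list. The median runs from -0.43 for endothelial markers to 0.43 for macrophage markers.

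Markers of cells other than fibres moved in both directions. Of 20 endothelial markers 3 fell and 0 rose (10 fell adjusted over the list alone), with Gpihbp1, which anchors lipoprotein lipase on capillaries, down 2.09-fold, Icam2 1.74-fold and Emcn 1.51-fold. The endothelial median was -0.43 (camera adjusted p = 0.000179; adjusted p = 0.580 with an estimated correlation). Of 11 smooth muscle and pericyte markers 4 fell and 1 rose (5 fell and 1 rose adjusted over the list alone), including Acta2 (1.54-fold lower) and Rgs5 (1.52-fold lower), while Lmod1 rose 1.70-fold; camera gave adjusted p = 0.0398, adjusted p = 0.515 with an estimated correlation and 0.0518 under cyclic loess (median -0.23 against -0.35). Of 14 Schwann cell markers 2 fell, S100b (1.72-fold) and Mal (1.58-fold), and 4 fell adjusted over the list alone; camera gave adjusted p = 0.0327, adjusted p = 0.515 with an estimated correlation and 0.0687 under quantile normalization (median -0.26 against -0.34). Macrophage markers had a median of 0.43 with 0 of 23 rising and Cd163 falling 1.91-fold (0 and 0 adjusted over the list alone; camera adjusted p = 0.0105; adjusted p = 0.825 with an estimated correlation), and this call was lost under quantile normalization (median 0.46; adjusted p = 0.108) and cyclic loess (0.47; 0.0714). It was also lost without control animal 1 (median 0.21; adjusted p = 0.147), without knockout animal 3 (0.15; 0.123), in series B alone (0.27; 0.0814) and with array weights (0.053; 0.245). Of 10 satellite cell markers 0 rose and 1 fell, Calcr, by at least 1.34-fold (1 rose and 2 fell adjusted over the list alone), with a median of -0.21; the list did not pass camera (adjusted p = 0.465) but passed fry (adjusted p = 0.0182). The mean of the satellite cell markers differed by -0.21 (exact two-sided permutation p = 0.0286, the smallest possible, before any correction for 9 lists of cell markers). The same permutation test gave p = 0.0286 for smooth muscle and 0.0571 for both endothelial and Schwann markers. It gave p = 0.257 for macrophage markers, and no remaining list gave less than 0.171. Of 4 blood cell genes, too few for a list test, 0 rose and 1 fell (2 fell adjusted over the list alone), with a median of -0.55. Alas2, which begins haem synthesis in red cells, fell 2.06-fold (adjusted p = 0.019, limma). Among 16 fibroblast and 12 tendon markers none rose or fell by limma, over all genes or adjusted over the list alone; at an unadjusted p the smallest were Mfap5 (p = 0.012) and Thbs4 (p = 0.0079). Xist and Kdm5d, the measured sex-linked genes, did not pass, at -0.15 and 0.09.

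Genes of stress, growth, the cell cycle and inflammation changed in both directions. Timp1, an inhibitor of matrix proteases, rose 4.4-fold and was the only 1 of 37 extracellular matrix genes to change, over all genes and adjusted over the list alone. Among 36 oxidative stress genes, Gpx3 fell 2.66-fold, Gstp1 1.83-fold and Prdx3 1.43-fold while Gpx1 rose 1.99-fold (4 fell and 1 rose; 8 and 2 adjusted over the list alone). Of 29 hypertrophy genes 5 rose and 1 fell (6 and 4 adjusted over the list alone), including Fst, an inhibitor of myostatin (2.46-fold higher), Akt1 (1.98-fold higher) and Irs2 (1.79-fold higher). Of 24 atrophy genes the ubiquitin ligase Trim63 fell 1.78-fold and Foxo4 1.54-fold while Map1lc3a rose 1.54-fold (1 rose and 3 fell adjusted over the list alone). Rrm2 rose 2.77-fold and Kif11 1.61-fold among 24 cell cycle genes, and Mcm2 fell 1.43-fold (4 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.0393; adjusted p = 0.515 with an estimated correlation; 0.0973 under quantile normalization and 0.0714 under cyclic loess, with medians of 0.21, 0.20 and 0.23 in turn). The interleukin receptor Il6ra rose 2.61-fold (log2 fold change 1.38, with 0.19 in its other row) and Socs3 1.72-fold among 26 inflammation genes, and Nfkbia fell 2.16-fold (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0456; adjusted p = 0.515 with an estimated correlation; 0.135 under quantile normalization and 0.109 under cyclic loess, with medians of 0.081, 0.10 and 0.12 in turn). Nfkbia was higher in control animals 2 and 3 (15.34 and 15.15, log2) than in control animals 1 and 4 (14.19 and 14.25). Usp18 rose 3.11-fold and Iigp1 1.82-fold among 24 interferon-stimulated genes, with 2 higher and 1 lower adjusted over the list alone.

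Leaving out 1 animal ended the calls of Chaf1a and Impact whichever of the 8 it was, that of H2aw for 7 of them, those of Cd163, Emcn and Lmod3 for 6, Rplp0 for 5, and Chrng, Kif11, Map1lc3a, Irs2, S100b and Mal for 4. It ended those of Lmod1, Mdh1 and Nfkbia for 3 animals, Mcm2, Pln and Alas2 for 2, and Arrdc2 and Ndufa4 for 1. In all, 13 of the 41 tested lists passed camera with the preset correlation, 6 up and 7 down, and 0 passed with an estimated correlation, while fry called 8 of these 13 and 3 others. The 5 that fry did not call were the endothelial (adjusted p = 0.0611), oxidative phosphorylation (0.0772), ribosomal protein (0.0706), neuromuscular junction (0.0706) and macrophage (0.486) lists. The 3 others were satellite cell markers, fatty acid and triglyceride synthesis (adjusted p = 0.00976, downward) and imprinted genes (0.0337, upward, with a mean of 0.19 but a median of -0.19). The camera calls of lists were also lost on leaving out 1 animal, for the neighbours of Hira with 5 of the 8 animals, smooth muscle and inflammation with 4, Schwann and cell cycle with 3, macrophage with 2, and slow-twitch, neuromuscular junction and oxidative phosphorylation with 1. Under quantile normalization and cyclic loess 6 lists passed, and 5 of the 34 other splits of the animals gave as many lists as the real one.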

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

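All tests of explanations in this part were chosen after the results were seen. By Dixon's ratio, chance flags about 1 in 20 unselected groups of 4 animals. Most named genes were picked by small p or by large change without overlap, so that rate is no fair reference for them. Of 352 groups of 4 animals examined, 7 held an animal far from the other 3 by this ratio, 1.99%. On the log2 scale these were Tbx1 in knockout animal 4 (11.5, others 12.09 to 12.14), Tmem74b in knockout animal 4 (5.67, others 5.28 to 5.31), Tmem132b in knockout animal 3 (9.14, others 8.31 to 8.41), Ccdc69 in knockout animal 4 (8.94, others 8.73 to 8.76), Egr3 in control animal 3 (8.19, others 8.68 to 8.75), Xist in knockout animal 3 (7.25, others 7.67 to 7.74) and the mean of the dystrophin complex and sarcolemma repair list in knockout animal 2 (13.2, others at most 13.02). Of 6046 rows without a gene symbol, which no comparison used, 265 passed the test when every row was treated as a feature, 119 higher and 146 lower.

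H19 rose 21.9-fold and Igf2 2.08-fold. More embryonic or regenerating fibres would raise the other members of that list too. The highest upper 95% limit among the 9 others was 1.43, for Actc1. This argues against a rise of the measured list as large as that of H19 (lower limit 4.11). It leaves such fibres open for Igf2 (lower limit 0.50). Markers need not rise alike, and Myh3, Myh8, Myog and Myod1 were not measured, so such fibres are not excluded for H19. Over all genes 0 of the 9 rose. Adjusted over the list alone, 2 rose, Tnnt2 (log2 fold change 0.53) and Mymk (0.45), and 2 fell, Chrng (-0.67) and Des (-0.35). A general rise of imprinted genes is not seen, since the 15 other imprinted genes had a median of -0.21 and 0 rose. The loss of HIRA in fibres, which the design names, stays open and untested.

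Tbx1, Tango2 and Arvcf lie near Hira and fell. Of the 40 measured genes around Hira 9 changed. With these 3 left out, since they prompted the test, 6 of the other 37 changed (16.2%), a higher share than in 91.3% of 16910 windows. This does not reach the 95% set for a change linked to the locus and leaves it open. The other windows kept all their changed genes, so the comparison is strict. With the 3 kept, the count lay above that of 98.1% of windows, but these genes had prompted the test. It is not 1 even drop, because the other 18 neighbours had a median of -0.054 relative to the median of all genes and 4 of the 9 changed genes rose. The animals were of mixed C57BL6/J and 129S1/SvImJ background, and only the knockout carried the null copy, so linked strain variants, a local effect of the deleted copy and a loss of HIRA cannot be told apart in this design.

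Of 20 endothelial, 11 smooth muscle and 14 Schwann markers 3, 4 and 2 fell and 0, 1 and 0 rose, with medians of -0.43, -0.35 and -0.34 (adjusted p = 0.580, 0.515 and 0.515 with an estimated correlation). Scaling that depends on brightness is argued against for the endothelial list, which stayed at -0.38 under cyclic loess (adjusted p = 4.5e-05), but not for smooth muscle (-0.23; adjusted p = 0.0518, though -0.25 and 0.0491 under quantile normalization) or Schwann markers (-0.23; adjusted p = 0.0419 under loess but 0.0687 under quantile normalization). A smaller share of all non-fibre cells would lower macrophage markers alike; macrophage minus endothelial markers moved by 0.80 on the log2 scale, but an exact two-sided permutation test gave p = 0.114, so this cannot be told apart from the spread of the animals. The same difference was computed for 4 other single lists and for the mean of 3 lists, and of these 6 the tendon list (0.51) and the mean (0.53) gave p = 0.0286, the smallest possible, before any correction for 6 tests. By genotype, endothelial, smooth muscle and Schwann cells carried a null copy of Hira in the knockout alone. An effect in these cells and one through the fibres cannot be told apart in this design. A loss of capillaries remains open and untested.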

How the results depend on the processing

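The floor at the 20th percentile and the removal of 2 arrays were chosen after seeing the data. Against 1647 changed genes (759 higher, 888 lower) and 13 lists, quantile normalization gave 2567, 1218, 1349 and 6, and cyclic loess 2454, 1318, 1136 and 6. All arrays with the animal as a random block gave 3149, 1334 and 1815 genes, the hybridisation number as a replicate block with it 2978, 1293 and 1685, and array weights 3609, 1276 and 2333; list tests were not run for both fits of all arrays. Arrays with the same hybridisation number deviated together little on average (mean r 0.06), although single pairs ranged from -0.63 to 0.75. Of 24 arrays, 10 correlated best with their own number. The mean for different numbers was -0.03. Deviations were taken from the mean of each animal, so that value is tied to the first mean and is no separate reference. The number was not taken to pair arrays. Series A alone, with 2 animals per group, gave 62, 51 and 11 genes and 8 lists, and series B alone 508, 311 and 197 genes; fewer animals enter these fits. No gene passed a test of a different effect between the series by limma (0 adjusted; 2065, or 11.6% of genes, at an unadjusted p under 0.05, where chance gives 5%). Ordinary t statistics gave 1089, 505 and 584 genes. The estimated correlation left 0 lists. Leaving out 1 animal or 1 hybridisation number gave 945 to 1693 changed genes, 522 to 727 higher, 418 to 966 lower and 7 to 14 lists; by over 1.5 times this moved the changed genes without control animal 1 (1062) or knockout animal 3 (945), the genes lower without control animal 1 (484), knockout animal 3 (418), knockout animal 4 (587) or hybridisation 2 (505), and the lists without control animal 1 (8) or knockout animal 4 (7). Median centring moved nothing, as the medians were already equal, and tests nothing. The cause of these differences was not tested. Hira did not pass in any alternative that held it, and was outside the filter on dim rows. Endothelial, fatty acid oxidation and ribosomal protein lists kept their calls in all 25 alternatives run with camera at the preset correlation, median centring among them, but fry did not call the endothelial (adjusted p = 0.0611) or the ribosomal protein list (0.0706). Of the named genes' values under alternatives, 3159 kept direction and call, 538 lost the call, 28 gained it and 1 reversed, Kdm5d in series A alone (-0.087), whose difference never passed. Quantile normalization kept 96.6% of the 1647 calls and cyclic loess 98.1%. The low end of the arrays limits what can be said of dim genes: 37 rises were dim in control and 31 falls in knockout muscle.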

Other observations

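The split counts below were planned; the tests of cilium genes and of long non-coding RNAs were chosen after the result was seen. Genes of the adipocyte, lipid synthesis and cholesterol synthesis lists changed in both directions, and none of these lists passed camera (adjusted p = 0.465, 0.246 and 0.816). Of 20 adipocyte markers 3 rose and 4 fell (3 and 7 adjusted over the list alone): Ucp1, the uncoupling protein of brown fat, rose from an intensity of 125, about the level at or below which genes were treated as dim, to 610, Thrsp rose 1.99-fold and the lipid droplet protein Cidea 1.94-fold, while Pck1 fell 3.34-fold. Of 19 fatty acid and triglyceride synthesis genes 1 rose and 3 fell (2 and 5 adjusted over the list alone), and Dgat2, which makes triglyceride, fell 2.09-fold and Lpin1 1.48-fold. Of 19 cholesterol synthesis genes 2 rose and 4 fell, with the same counts adjusted over the list alone: Mvd rose 2.08-fold and Hsd17b7 1.47-fold while the falls included Fdft1 (1.47-fold) and Fdps (1.45-fold). Of 25 p53 target and senescence genes 4 rose and 2 fell, with the same counts adjusted over the list alone, and the list did not pass camera (adjusted p = 0.139). Zmat3 rose 1.68-fold and Cdkn1a 1.41-fold, and Gadd45g (3.97-fold) and Eda2r (1.55-fold) fell. Gadd45g was higher in control animals 2 and 3 (15.31 and 15.02, log2) than in control animals 1 and 4 (12.83 and 13.57). Leaving out 1 animal ended the calls of Cdkn1a for 7 animals, Zmat3 for 5, and Gadd45g, Fdft1 and Fdps for 4.

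Rises of 2-fold or more outnumbered falls among brighter genes as well. Of genes whose mean intensity over all arrays was above 1000, 124 rose and 53 fell by that much, 70.1% rises (exact 95% interval 62.7% to 76.7%), against 72.3% over all genes. Genes are not independent replicates, so these intervals are a description. A930003A15Rik and Camk2n2, chosen after their values were seen, rose near Hira, by 2.74 and 0.84 on the log2 scale.

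Pifo, among the largest rises named, and some genes seen further down the ranking belong to cilia. Axoneme and motile cilium genes as a group did not pass the test. Of 131 measured, 10 rose and 2 fell, with a median log2 fold change of -0.066 (camera p = 0.141, and 0.576 with an estimated correlation). With the genes seen first left out, 124 measured genes gave a camera p of 0.839, and 3 rose and 2 fell. Among changed genes, rises made up a larger share of long non-coding RNA genes than of protein-coding genes, 35 of 53 against 722 of 1584 (66.0% against 45.6%; exact two-sided Fisher p = 0.00465). Per measured gene the share that fell was lower, 2.76% of 652 against 5.17% of 16667 (exact two-sided Fisher p = 0.00461). The share that rose, 5.37% against 4.33%, did not pass (p = 0.204, exact two-sided Fisher). Genes are not independent replicates and the gene types were not matched on brightness, so these Fisher tests are a description.

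Of the 35 splits of the 8 animals into 4 and 4, 1, the real one, gave as many as 1647 changed genes. The highest of the others gave 2. This argues against chance for that count, but 1 of 35 is the smallest share these splits can give, so chance is not excluded. The splits also cannot separate genotype from anything else shared by the animals of a group. For the gene lists 6 of the 35 splits, the real one included, gave 13 or more, and the highest other gave 16, in the split that follows the series of animal numbers. Chance cannot be excluded for the number of lists; with the series as a block 13 lists passed. Against 10000 random lists matched on brightness, the median of the endothelial list lay at percentile 0, fatty acid oxidation at 0.03 and ribosomal proteins at 99.7. Macrophage markers lay at 100, cell cycle genes at 99.99 and the neighbours of Hira at 12.1. Random lists ignore the correlation of genes within a list, so extreme percentiles can overstate the evidence. That correlation was estimated at 0.53 for the endothelial, 0.23 for the fatty acid oxidation and 0.27 for the ribosomal protein list. With it, camera gave adjusted p = 0.580, 0.515 and 0.515 in turn.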
